A study of Homo sapiens with 6 samples.

How the data were processed

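RNA was extracted from 6 AGS cultures, selected for poly-A tails and sequenced, per the labels' protocols. The deposited table held FPKM for 58735 genes in 6 columns, 1 per library. The authors made these FPKM values. The submitters' processing notes name HISAT2, StringTie and the build GRCh38 without a version, role or order. The strand setting, the filters and the treatment of reads that match several genes are not given in the sources used here. Samples were grouped by their titles, which name the siRNA and the replicate number. The labels call the replicates biological.

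The gene identifiers of the table all matched GENCODE 29 (Ensembl 94), from which biotypes, coordinates and exon lengths were taken. Each FPKM times the union exon length of its gene was a whole multiple of 1 step per library, for 100% of the values above 0 at a tolerance of 0.001 fragments. The table therefore rests on whole fragments per gene. The recovered fragments added up to 14839197 to 16562501 per library. The divisor behind the FPKM was 0.971 to 1.05 times that sum, for a reason the sources used here do not give. The recovered fragments were used for depth, for low genes and for 1 alternative, not for the main test. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom between the libraries of a group was 4.29 to 54.6.

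The comparison of siRBM8A with siNC was made with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with the variance trend and two-sided tests, for the 12678 genes with a mean of at least 1 FPKM over the 6 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. A fold change is on the log2(FPKM + 1) scale, which understates the change of low genes. RBM8A was also tested by exact permutation. Gene lists were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 31 lists that had at least 5 measured members. An estimated correlation and the fry test were run beside it. With an estimated correlation, camera takes its degrees of freedom from the few libraries and not from the genes. This alone raises its p. The 34 lists held 620 genes, of which 619 were found in the table. The test, the lists, the named-gene rule and most alternatives were set before the data were examined. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

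The text names RBM8A, its partners MAGOH, MAGOHB, EIF4A3 and CASC3, and the 10 highest and 10 lowest protein-coding genes by log2 fold change. Those 20 had an adjusted p under 0.05, no overlap between the groups and a mean of at least 5 FPKM in the higher group. Up to 4 members with the smallest adjusted p under 0.05 were named from each called list and up to 2 from each other list. Genes named outside this rule are marked as named after their values were seen.

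Whether the replicate numbers pair the libraries was checked before fits were compared. The deviations from the group means of libraries with the same number correlated across genes at 0.507, 0.663 and 0.102 for replicates 1, 2 and 3. All 3 were above 0.1, so the numbers were treated as pairing the libraries. They are not 3 independent results, because the deviations within a group sum to 0. Replicate 2 of each group correlated negatively with replicates 1 and 3 of the other group. The match could therefore also come from a single trend along which the libraries happen to be ordered alike. This pairing comes from the data, since the labels state no shared passage, day or batch for a number. It is weak for replicate 3, whose correlation had a jackknife SE of 0.0252 over chromosomes: siNC replicate 3 correlated more with siRBM8A replicate 1, at 0.258, and siRBM8A replicate 3 more with siNC replicate 1, at 0.187. The main test has no block, and a fit with the replicate number as a block is given for the counts of genes and of the members of called lists, and beside other results where it changes the call of a list or a named gene.

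Alternatives covered the pseudocount, the FPKM filter, scaling, the variance model, array weights, the replicate block, protein-coding genes, thresholds and leaving out each library. Added after the data were seen were a GC correction with and without the block, limma-voom on the recovered fragments with and without the block, leaving out both replicate 2 libraries, and the block with an estimated correlation or a 1.5-fold minimum. The GC correction subtracted from each library a loess curve (span 0.3) of its deviation from the gene mean on the GC content of the longest transcript. Such a correction also removes any real change that follows GC content.

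The test was checked on simulated FPKM for siRBM8A against siNC. Without a GC trend, on 12688 genes, the main test recovered 16.9% of genes changed 1.5-fold, 71.2% of those changed 2-fold and 98.4% of those changed 4-fold, with 15 false calls among 136. The replicate block recovered 4.62%, 68.2% and 98.4% there, with 23 false calls among 134. With a GC trend shared by the replicate numbers, on 12708 genes, the main test recovered 0%, 19.7% and 95.3%, with 4 false calls among 78. The replicate block recovered 7.46%, 65.2% and 96.9% with that trend, with 17 false calls among 127. The simulated trend was the same in both groups, so it cancels in the comparison. In the data the log2 fold change itself correlated with GC content, at 0.330. False calls from a trend that differs between the groups were therefore not measured.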

Results

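Polyadenylated RNA was profiled in AGS cells, an established human gastric adenocarcinoma line, 48 h after transfection with an siRNA against RBM8A (siRBM8A) or a control siRNA (siNC). Each group held 3 biological replicates, and all 6 libraries carried 1 batch label. The values were FPKM for 58735 genes. The libraries rested on 14839197 to 16562501 fragments assigned to genes, as recovered from the FPKM steps. At the shallowest depth, siRBM8A replicate 3, a floor of 3 fragments corresponded to 0.0987 FPKM for a gene with 2 kb of exon. The floor covers counting error only. The design asked which transcripts differed between cells with and without the RBM8A siRNA.

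The siRBM8A cells held 20.5% of the RBM8A transcript level of the siNC cells. RBM8A encodes Y14, a core protein of the exon junction complex, which is deposited on spliced mRNA. Its level was 14.4 ± 1.08 FPKM in siNC and 2.95 ± 0.63 FPKM in siRBM8A (mean ± SD, n = 3 each), and every siRBM8A library lay below every siNC library. The partners MAGOH, MAGOHB and EIF4A3 and CASC3 were not called in the main test, and MAGOH and CASC3 gained a call in some alternatives. RBM8A (ENSG00000265241) lies on the minus strand of chromosome 1, from 145917714 to 145927678 in GRCh38, and its annotated transcripts have up to 7 exons. The log2 fold change was -1.97 (SE 0.142, adjusted p = 0.00544, limma). The exact two-sided permutation test of the FPKM gave p = 0.1, the smallest that 3 against 3 libraries allow. Without siRBM8A replicate 3 the log2 fold change was -2.05 and the adjusted p 0.0544, the highest of a range over the alternatives that began at 9.16e-10. Exons of RBM8A overlap a gene on the opposite strand over 25.0% of their bases, and the strand setting of the counting is not given in the sources used here.

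MAGOH, the direct binding partner of Y14, was at 23.4 ± 1.70 FPKM in siNC and 25.9 ± 2.57 FPKM in siRBM8A (log2 fold change 0.14, adjusted p = 0.468). With the GC correction its log2 fold change was 0.22 and its adjusted p 0.0455, and 0.0366 with the block as well, in a range over the alternatives from 0.0286 to 0.754. EIF4A3, the RNA helicase that anchors the complex, was at 30.2 ± 3.64 and 31.9 ± 4.74 FPKM (log2 fold change 0.07, adjusted p = 0.784). EIF4A3 was called in 1 alternative, with array weights, whose estimation stopped before convergence (adjusted p = 0.0119, range over the alternatives up to 0.963). MAGOHB, a near-identical paralog of MAGOH whose reads may be shared with it, was at 4.31 ± 0.479 and 4.00 ± 0.905 FPKM (log2 fold change -0.10, adjusted p = 0.728). CASC3 was at 13.2 ± 0.764 and 9.90 ± 0.768 FPKM (log2 fold change -0.38, adjusted p = 0.0712). With the replicate block the adjusted p of CASC3 was 0.00762, in a range over the alternatives from 0.000165 to 0.235. With the GC correction its log2 fold change was -0.42 and its adjusted p 0.00178, and 0.00395 with the block as well. Of the 13 measured genes on the list of complex partners 0 were called by limma, with 2 at an unadjusted p under 0.05, and the list was not called (adjusted p = 0.444, camera). Without siRBM8A replicate 2 the signs of MAGOHB and EIF4A3 turned, to log2 fold changes of 0.0445 and -0.0316.

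**Figure D1:**
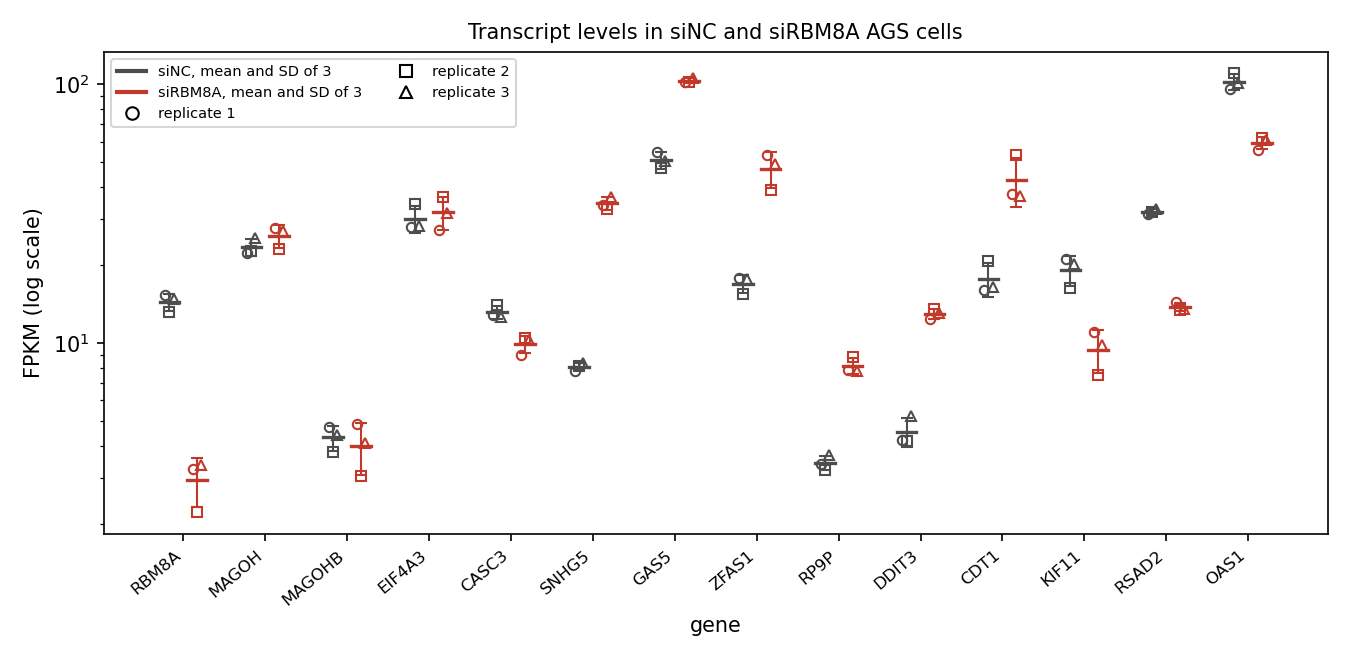
FPKM (log scale) of 14 named genes in each library, with siNC in grey and siRBM8A in red, marker shapes for the replicate number, and bars for the mean and SD of 3 libraries. RBM8A falls from 14.4 to 2.95 FPKM, SNHG5 rises from 8.11 to 34.6 FPKM, and the 2 groups of MAGOH, MAGOHB and EIF4A3 overlap.

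Across the transcriptome, 709 of 12678 tested genes changed, 305 upward and 404 downward. CTGF (CCN2), a secreted matricellular protein, and HMOX1, which degrades haem, were among the protein-coding genes that rose most. The acute-phase protein gene ORM2, the transglutaminase gene TGM2 and the endothelial receptor gene HEG1 were among those that fell most. At least 2-fold changes were found in 90 genes, 50 upward and 40 downward. The median log2 fold change was 0.72 among called genes that rose and -0.66 among those that fell. Without overlap between the groups were 3969 genes, 31.3% of those tested, and all 709 called genes were among them. Chance gives 10% for a single gene. Genes share trends over the libraries, so the share in 1 dataset can exceed 10% without an effect of the siRNA.

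The counts moved strongly with how the spread between libraries was modelled. With the replicate block, 5096 genes were called, 2392 upward and 2704 downward, and all 709 genes were among them. The at least 2-fold count was 133 with the block. Leaving out 1 library changed the 709 calls to 12 without siNC replicate 1, to 132 without siNC replicate 2, to 8 without siNC replicate 3, to 398 without siRBM8A replicate 1 and to 2 without siRBM8A replicate 3. The at least 2-fold count fell from 90 to 12 without siNC replicate 1, to 8 without siNC replicate 3 and to 2 without siRBM8A replicate 3. The 2 genes called without siRBM8A replicate 3 were CTGF and SNHG5, both upward. Of the 69 named genes other than RBM8A, 59 lost their call without siNC replicate 1, 35 without siNC replicate 2 and 60 without siNC replicate 3. Without siRBM8A replicates 1, 2 and 3, 18, 4 and 63 of the 69 lost it. The 69 include MAGOH, MAGOHB, EIF4A3 and CASC3, which had no call in the main test to lose. The balance of directions was not stable: 43.0% of the 709 calls were upward, against 59.0% (468 upward, 325 downward) after scaling the libraries to equal FPKM sums and 36.5% (326 upward, 568 downward) among protein-coding genes fitted alone. Of the at least 2-fold calls, 55.6% were upward, against 66.0% (64 upward, 33 downward) after that scaling. The upward majority at 2-fold turned among protein-coding genes alone (21 upward, 41 downward), without a filter on low values (27 upward, 32 downward) and without siRBM8A replicate 2 (43 upward, 52 downward).

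Among the 10 protein-coding genes with the highest fold changes, KRTAP3-1, a hair keratin-associated protein gene, rose from 2.15 ± 0.679 to 12.6 ± 2.18 FPKM (log2 fold change 2.12, SE 0.185, adjusted p = 0.00860). CTGF rose from 22.7 ± 1.01 to 88.8 ± 7.07 FPKM (log2 fold change 1.92, SE 0.0990, adjusted p = 0.00178). HMOX1 rose from 108 ± 14.9 to 361 ± 55.6 FPKM (log2 fold change 1.73, SE 0.150, adjusted p = 0.00860). The others were TEX19, DDIT3, CCNB1IP1, CDT1, DDIT4, METTL27 and TENT5A, with log2 fold changes from 1.86 for TEX19 to 1.12 for TENT5A. Genes on the opposite strand overlap 43.8% of the exon bases of TEX19, 31.6% of those of DDIT3 and 41.2% of those of DDIT4, so their values are uncertain.

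RBM8A had the lowest fold change of all protein-coding genes that met the naming rule. ORM2 fell from 5.66 ± 1.57 to 0.886 ± 0.500 FPKM (log2 fold change -1.83, SE 0.253, adjusted p = 0.0160), on 211 fragments in the siNC libraries and 32 in the siRBM8A libraries. TGM2 fell from 9.76 ± 1.85 to 2.76 ± 0.550 FPKM (log2 fold change -1.51, SE 0.163, adjusted p = 0.0108). HEG1 fell from 13.3 ± 0.827 to 4.37 ± 0.209 FPKM (log2 fold change -1.42, SE 0.0924, adjusted p = 0.00435). The others were PHLDA2, BIRC3, S100A16, GSTM4, SAMD9L and CLDN2, with log2 fold changes from -1.43 for PHLDA2 to -1.26 for CLDN2. ORM2 and GSTM4 have close paralogs with which reads may be shared. Without siNC replicate 1, only RBM8A, CTGF, TEX19, HEG1 and GSTM4 kept a call among these 20 genes. Without siNC replicate 3 the genes that kept one were RBM8A, KRTAP3-1, CTGF, DDIT3 and HEG1.

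Of 31 gene lists tested with camera at its preset correlation, 13 were called, 6 upward and 7 downward. In every other split of the 6 libraries into groups of 3, camera at this setting called 4 to 11 lists. Its adjusted p alone is therefore not specific to the siRNA. The lists of nonsense-mediated decay targets, DNA replication, the ATF4 and integrated stress response, the unfolded protein response, hypoxia and p53 targets were higher in siRBM8A than other genes. The lists of interferon response, G2 and mitosis, mitochondrially encoded genes, oxidative phosphorylation, gastric and intestinal lineage, Wnt targets and NF-kB genes were lower. No list was called with an estimated correlation (0 of 31), and 5 had an unadjusted p under 0.05 there. The estimate was below the preset 0.01 for interferon response (0.00518), unfolded protein response (-0.0123), Wnt targets (-0.0257) and p53 targets (-0.0289). Higher correlation between members therefore does not account for the loss of those calls. The smaller degrees of freedom of that setting apply to every list. For the other called lists the estimate was above 0.01, from 0.0127 for DNA replication to 0.910 for mitochondrially encoded genes. With the replicate block and an estimated correlation 0 lists were called as well. The block leaves even fewer degrees of freedom, so that setting had little power to call any list and decides little. The self-contained test fry called 8 lists, all among the 13, and did not call those of G2 and mitosis (adjusted p = 0.0679), mitochondrially encoded genes (0.238), oxidative phosphorylation (0.0675), hypoxia (0.133) and NF-kB genes (0.133). No gene stood on more than 1 list.

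The list of targets of nonsense-mediated decay, the pathway that degrades transcripts with premature stop codons and in which the exon junction complex takes part, was higher in siRBM8A than other genes by camera at its preset correlation. Of 18 measured transcripts 9 rose and 0 fell, and 13 rose when adjusted over the list alone. By the fit with the replicate block, 15 rose and 0 fell. The median log2 fold change was 0.49 (adjusted p = 2.55e-09, camera). The adjusted p was 0.126 with an estimated correlation. SNHG5, a non-coding snoRNA host, rose from 8.11 ± 0.276 to 34.6 ± 1.96 FPKM (log2 fold change 1.97, SE 0.0907, adjusted p = 0.00165). GAS5, another snoRNA host, rose from 50.8 ± 3.67 to 103 ± 2.30 FPKM, and ZFAS1 from 17.0 ± 1.34 to 47.2 ± 7.47 FPKM. Exons of other genes overlap 20.9% of the ZFAS1 bases on its own strand and 26.1% on the other, so its value is uncertain. The transcribed pseudogene RP9P, which has a coding parent with similar sequence, rose from 3.44 ± 0.220 to 8.14 ± 0.587 FPKM. SNHG5 alone of these 4 kept a call without siNC replicate 1, without siNC replicate 3 and without siRBM8A replicate 3. Most of the 9 called transcripts, these 4 among them, were long non-coding RNA genes or a transcribed pseudogene. Of all 977 tested long non-coding RNA genes 56 rose and 13 fell, with a median log2 fold change of 0.10. The median of the 187 transcribed pseudogenes was 0.20. Whether the list rose beyond these classes was not tested. Of the 15 measured decay factors, NBAS fell (log2 fold change -0.68, adjusted p = 0.0160) and the others were not called, while 6 rose and 5 fell with the replicate block. The list of factors was not called (adjusted p = 0.783), and its median, 0.13, and mean, -0.01, differed in sign.

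Lists of stress genes were higher in siRBM8A than other genes by camera at its preset correlation. Of 16 measured genes of the ATF4 and integrated stress response, 4 rose and 0 fell, and 10 rose when adjusted over the list alone (median log2 fold change 0.55, adjusted p = 5.31e-05, camera). With an estimated correlation the adjusted p was 0.308. In the blocked fit 12 rose and 1 fell. DDIT3, the transcription factor CHOP, rose from 4.54 ± 0.587 to 13.0 ± 0.597 FPKM, and DDIT4, an inhibitor of mTORC1, rose from 20.3 ± 3.17 to 48.5 ± 12.4 FPKM. The other 2 were CARS, a cysteinyl-tRNA synthetase gene (log2 fold change 0.57), and PCK2 (log2 fold change 0.74). Of 16 unfolded protein response genes 4 rose and 0 fell, and 5 rose when adjusted over the list alone (median 0.31, adjusted p = 0.000415, camera). This adjusted p was 0.126 with an estimated correlation, and with the replicate block 11 members rose and 1 fell. HSPA5, the chaperone BiP of the endoplasmic reticulum, rose from 316 ± 8.30 to 481 ± 8.53 FPKM. PDIA4, a disulphide isomerase, rose from 209 ± 8.14 to 352 ± 8.27 FPKM. MANF and CRELD2 rose by log2 fold changes of 0.73 and 0.80. None of these 8 genes was called without siNC replicate 1 or without siRBM8A replicate 3, and DDIT3 alone was called without siNC replicate 3.

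By camera at its preset correlation, the list of replication genes was higher and that of mitotic genes lower in siRBM8A than other genes. Of 26 measured DNA replication genes, 4 rose and 0 fell, and 9 rose when adjusted over the list alone (median log2 fold change 0.31, adjusted p = 4.89e-05, camera). The adjusted p was 0.126 with an estimated correlation, and with the replicate block 15 rose and 0 fell. CDT1, which licenses replication origins, rose from 17.7 ± 2.63 to 42.7 ± 9.15 FPKM (log2 fold change 1.21, SE 0.173, adjusted p = 0.0177). E2F1, a transcription factor of the G1 to S transition, rose from 15.0 ± 2.48 to 28.7 ± 3.38 FPKM. FEN1 and MCM3 rose by log2 fold changes of 0.61 and 0.55. Of 24 genes of G2 and mitosis, 2 fell and 0 rose, and 7 fell when adjusted over the list alone (median -0.30, adjusted p = 0.000112, camera), and the adjusted p was 0.490 with an estimated correlation. With the block 17 fell and 0 rose. The spindle motor gene KIF11 fell from 19.2 ± 2.52 to 9.43 ± 1.76 FPKM, and the checkpoint kinase gene BUB1 from 21.6 ± 2.30 to 13.0 ± 1.81 FPKM. None of these 6 genes was called without siNC replicate 1, without siNC replicate 3 or without siRBM8A replicate 3. Neither the homologous recombination and checkpoint list (adjusted p = 0.671) nor the replication-dependent histone list (adjusted p = 0.216) was called. The histone list was called with array weights, whose estimation stopped before convergence (adjusted p = 0.0347, range over the alternatives up to 0.728).

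The list of interferon-stimulated genes was lower in siRBM8A than other genes by camera at its preset correlation. Of 26 measured genes, 9 fell and 0 rose, and 18 fell when adjusted over the list alone (median log2 fold change -0.49, adjusted p = 1.92e-07, camera). The adjusted p was 0.121 with an estimated correlation, and with the replicate block 20 fell and 1 rose. RSAD2, the antiviral protein viperin, fell from 32.1 ± 0.772 to 13.8 ± 0.507 FPKM (log2 fold change -1.16, SE 0.0857, adjusted p = 0.00570). OAS1, an oligoadenylate synthetase, fell from 102 ± 7.11 to 59.4 ± 3.37 FPKM. The RNA sensor gene IFIH1 fell by 0.60 on the log2 scale, and OAS2 fell by 0.55. RSAD2 kept its call without siNC replicate 1, and none of the 4 was called without siNC replicate 3 or without siRBM8A replicate 3. Of 11 NF-kB and inflammatory genes 2 fell and 0 rose, and 3 fell when adjusted over the list alone (median -0.20, adjusted p = 0.0449, camera). The adjusted p of the list was 0.612 with an estimated correlation. It was 0.126 with the replicate block, where 4 members fell and 1 rose, 0.147 without siNC replicate 2, 0.236 without siRBM8A replicate 1 and 0.0827 without siRBM8A replicate 3, in a range that began at 0.00260. The 2 that fell were BIRC3, an inhibitor of apoptosis (log2 fold change -1.40), and TNFAIP3, the feedback inhibitor A20 (log2 fold change -0.85).

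**Figure D2:**
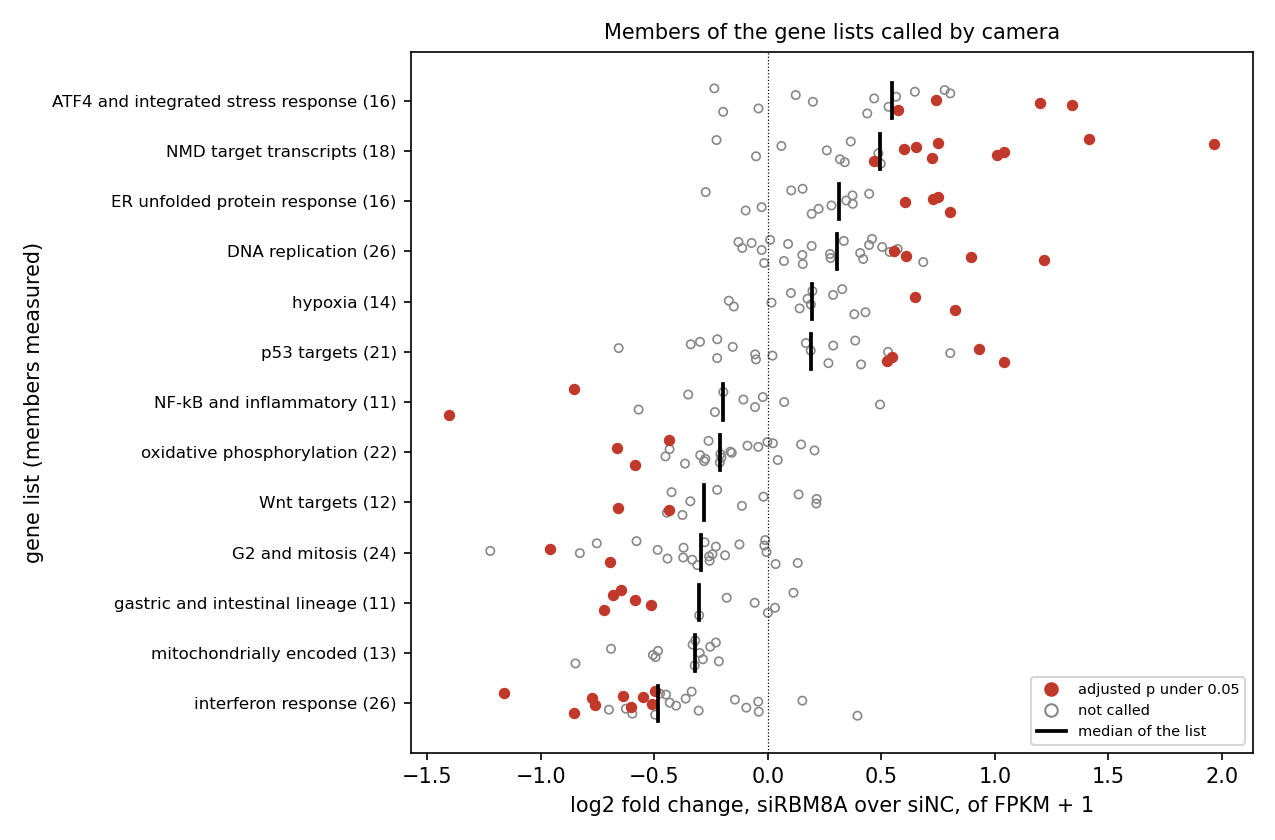
Log2 fold change (siRBM8A over siNC, FPKM + 1) of each measured member of the 13 lists called by camera, with red points for members at an adjusted p under 0.05, open points for the others and black bars for list medians. List medians run from -0.49 for the interferon response to 0.55 for the ATF4 and integrated stress response, and no list has red points on both sides of 0.

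Lists of mitochondrial and lineage genes were lower than other genes by camera at its preset correlation. All 13 mitochondrially encoded mRNAs lay below 0 (median log2 fold change -0.32, adjusted p = 0.00163, camera), but 0 were called by limma, with 5 at an unadjusted p under 0.05, and 2 fell when adjusted over the list alone. The adjusted p of this list was 0.728 with an estimated correlation, which was 0.910 between its members, 0.238 with fry and 0.106 after quantile normalization, in a range over the alternatives that began at 3.86e-06. In the blocked fit 7 fell. The list median was -0.337, -0.550 and -0.104 in the pairs of replicates 1, 2 and 3, so its size rested much on replicate 2. These mRNAs made up 3.75% to 4.49% of fragments in the siNC libraries and 2.75% to 4.02% in the siRBM8A libraries. In both groups replicate 2 had the lowest share. Of 22 nuclear oxidative phosphorylation genes 3 fell and 0 rose, and 4 fell when adjusted over the list alone (median -0.21, adjusted p = 0.00223, camera), and the adjusted p was 0.394 with an estimated correlation. With the block 14 fell and 1 rose, and fry gave an adjusted p of 0.0675. ATP5F1A, an ATP synthase subunit gene, fell from 24.9 ± 0.464 to 16.3 ± 0.332 FPKM. NDUFS1 and UQCRFS1 fell by 0.67 and 0.44 on the log2 scale. Of 11 gastric and intestinal lineage genes, 5 fell and 0 rose, also when adjusted over the list alone, and 7 fell with the replicate block (median -0.30, adjusted p = 0.00338, camera). The adjusted p was 0.490 with an estimated correlation and 0.0570 without siNC replicate 2, and 0.000496 at its lowest. CTSE, the gastric protease cathepsin E, fell from 278 ± 17.5 to 169 ± 6.66 FPKM, and the transcription factor genes SOX2 and GATA6 fell by 0.68 and 0.52. LGALS4 fell by 0.59, and VIL1, named after its values were seen, fell by 0.65. None of these 8 genes was called without siNC replicate 1, siNC replicate 3 or siRBM8A replicate 3, and VIL1 kept its call only without siRBM8A replicate 2.

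The remaining 3 called lists were those of hypoxia, Wnt targets and p53 targets. Of 14 hypoxia genes 2 rose and 0 fell, also when adjusted over the list alone (median log2 fold change 0.19, adjusted p = 0.0102, camera). The adjusted p of the list was 0.394 with an estimated correlation, 0.0571 without siNC replicate 2 and 0.128 without siRBM8A replicate 1, in a range that began at 0.000399. The 2 that rose were NDRG1 (log2 fold change 0.65) and ANKRD37 (log2 fold change 0.82), and with the replicate block 6 rose and 0 fell. Genes on the opposite strand overlap 35.2% of the exon bases of ANKRD37. Of 12 Wnt target genes 2 fell and 0 rose, and 6 fell when adjusted over the list alone (median -0.28, adjusted p = 0.0162, camera). The adjusted p of the list was 0.271 with an estimated correlation, 0.0676 with the replicate block, where 7 members fell and 1 rose, 0.0698 without siNC replicate 2 and 0.0874 without siRBM8A replicate 1, in a range that began at 0.000212. The 2 that fell were DKK1, a secreted Wnt inhibitor that fell from 159 ± 8.34 to 100 ± 9.02 FPKM, and CD44 (log2 fold change -0.44). Of 21 p53 target genes 4 rose and 0 fell, and 7 rose and 1 fell when adjusted over the list alone (median 0.19, adjusted p = 0.0397, camera). The adjusted p of the list was 0.293 with an estimated correlation, 0.0517 with the replicate block, where 11 members rose and 5 fell, 0.0699 without siNC replicate 2 and 0.104 without siRBM8A replicate 1, in a range by camera that began at 0.00676, and fry gave 0.00166. BBC3, the pro-apoptotic protein PUMA, rose from 36.6 ± 7.63 to 76.5 ± 15.7 FPKM, and PLK3, BTG2 and DDB2 rose by log2 fold changes of 0.93, 0.53 and 0.54.

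The other 18 tested lists were not called. With the replicate block more of their members passed the test, in both directions on most lists: 3 up and 13 down of the splicing factors, 4 up and 10 down of the apoptosis regulators, 5 up and 1 down of the NRF2 targets, 3 up and 6 down of the TGF-beta and BMP targets, and 4 up and 3 down of the YAP and TEAD targets. Over all 12678 tested genes 2392 rose and 2704 fell with the block. Blocked member counts near those shares, here or above, are not particular to a list. The splicing factor list had an adjusted p of 0.0637 (median log2 fold change -0.20, camera), and 0.0261 with the replicate block, in a range over the alternatives from 0.00790 to 0.728. With the GC correction its median was -0.019 and its adjusted p 0.360, and 0.527 with the block as well. One of its 25 measured genes, PRPF8, a core protein of the spliceosome, fell from 42.9 ± 3.96 to 25.2 ± 3.69 FPKM. Lists with members that passed the test in both directions were those of TGF-beta and BMP targets (1 up, 3 down; adjusted p = 0.207), YAP and TEAD targets (2 up, 1 down; adjusted p = 0.207) and MAPK feedback genes (1 up, 1 down; adjusted p = 0.789). For the TGF-beta and BMP list the adjusted p was 0.0291 with the GC correction and 0.0301 with the block as well, in a range over the alternatives up to 0.728. CDKN2B, an inhibitor of cyclin-dependent kinases, rose from 8.94 ± 0.154 to 19.3 ± 1.11 FPKM, and ID2 fell from 46.9 ± 3.81 to 23.3 ± 3.09 FPKM. ID1 (log2 fold change -0.58), SMAD6 (log2 fold change -0.69) and CRIM1 (log2 fold change 0.45), named after their values were seen, were the further members, beside MYOF (log2 fold change -0.72), SPRY1 (log2 fold change 0.58) and SPRY4 (log2 fold change -0.45). With 1 library left out, ID1 and CRIM1 kept a call only without siRBM8A replicate 2, and SMAD6 only without siRBM8A replicate 1 or 2. Single members changed on the lists of NRF2 targets (HMOX1), apoptosis regulators (PMAIP1, log2 fold change 0.52) and epithelial genes (TJP1, log2 fold change -0.53). On the glycolysis list HK1 and PFKM fell by 0.73 and 0.54. The adjusted p of these 4 lists was 0.135, 0.458, 0.789 and 0.462. Without a filter on low values the NRF2 list was called (adjusted p = 0.0170, range over the alternatives up to 0.394). The epithelial list had a median of 0.02 and a mean of -0.03, of opposite sign.

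No member was called by limma on 10 of the tested lists, which held 153 measured genes, 28 of them at an unadjusted p under 0.05. Besides those given above, these were the lists of cytosolic ribosomal proteins (adjusted p = 0.284), lysosome and autophagy (0.358), immediate early genes (0.659), mesenchymal genes (0.659), PI3K, AKT and mTOR components (0.671) and cholesterol synthesis (0.783). The ribosomal protein list was called with limma-voom and the block (adjusted p = 0.0279) and with array weights (0.0352), in a range over the alternatives up to 0.781. The marker lists of other cell types were too short to test. Of the immune markers 3 were measured, and LYZ, which gastric epithelium also expresses, fell from 139 ± 9.24 to 98.9 ± 7.22 FPKM (adjusted p = 0.0432). Of the fibroblast markers 3 were measured, and PDGFRA fell from 2.43 ± 0.410 to 0.954 ± 0.167 FPKM (adjusted p = 0.0297). LYZ and PDGFRA were named after their values were seen. LYZ lost its call whichever of the 6 libraries was left out, and PDGFRA kept it only without siRBM8A replicate 1 or 2. Of the endothelial markers 0 passed the FPKM filter.

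Libraries differed within each group by a trend with transcript GC content. The deviation of a library from its group mean correlated across genes with GC content at -0.535, 0.656 and -0.265 for siNC replicates 1, 2 and 3, and at -0.670, 0.737 and -0.301 for siRBM8A replicates 1, 2 and 3. Genes are not independent replicates. The log2 fold change correlated with GC content at 0.330, and at 0.153, 0.405 and 0.275 in the pairs of replicates 1, 2 and 3. The median GC content was 52.9% for the genes that rose and 47.1% for those that fell. With the GC trend removed from each library, 4024 genes were called, 699 of the 709 among them. With both replicate 2 libraries left out, the count was 1827, with 682 of the 709.

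**Figure D3:**
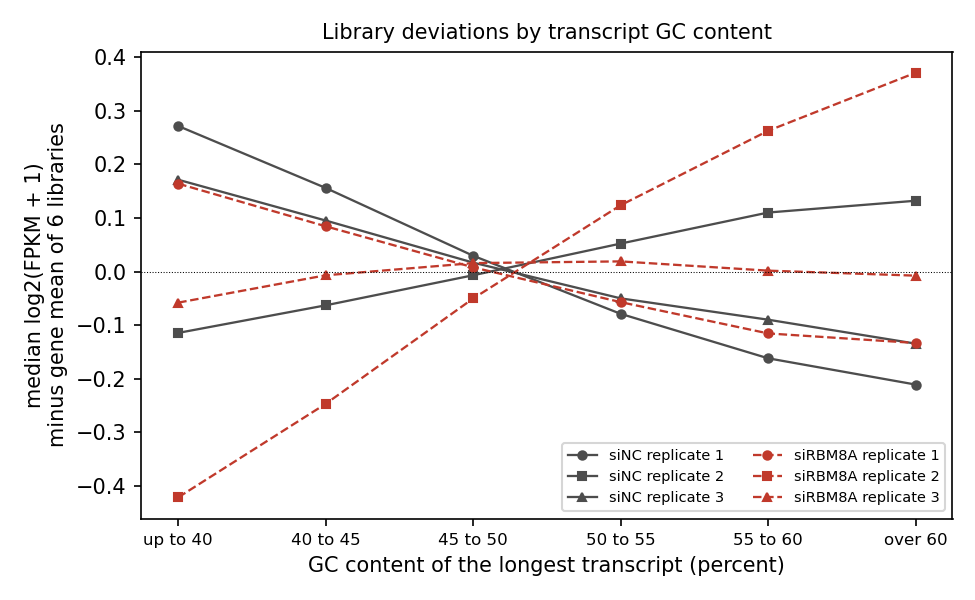
Median deviation of log2(FPKM + 1) from the gene's mean over the 6 libraries, by GC content of the longest transcript, with siNC as solid grey lines, siRBM8A as dashed red lines and marker shapes for the replicate number. The replicate 2 libraries rise with GC content in both groups, from -0.42 to 0.37 for siRBM8A replicate 2 and from -0.11 to 0.13 for siNC replicate 2, while replicate 1 falls in both.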

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

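The test of the low genes was chosen after the result was seen. Below the filter of 1 FPKM, where no comparison was made, 15 genes had 0 fragments in all siNC libraries and at least 3 in each siRBM8A library. The reverse was seen for 3 genes. They were looked at because they lay outside the comparison. Their control level of 0 is part of how they were chosen. Of the 15, 5 were protein-coding: ZFHX4, GRK7, TEKT3, SMOC1 and C17orf98, named after their values were seen. ZFHX4 had 25, 8 and 12 fragments in siRBM8A replicates 1, 2 and 3, and SMOC1 had 16, 15 and 8. Of the 10 splits of the 6 libraries into groups of 3, 1 gave as many such genes, the real one. The highest count in another split was 4, and 10 splits are too few for a share under 0.05.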

How the results depend on the processing

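Alternatives added after the data were seen were the GC correction, limma-voom, leaving out both replicate 2 libraries, and the block with the GC correction, an estimated correlation or a 1.5-fold minimum. Where no cause is named below, the cause was not tested. The 709 changed genes became 268 without a filter on low values (more genes tested), 20 at an adjusted p under 0.01, 8992 with array weights (whose estimation stopped before convergence), 5096 with the replicate block, 4024 with the GC correction, 5179 with the block and the GC correction, 6145 with limma-voom and the block, and 1827 without both replicate 2 libraries. Leaving out 1 library gave 2 to 628 genes, the lowest without siRBM8A replicate 3. The at least 2-fold count of 90 became 178 with a pseudocount of 0.1 FPKM and 16 with one of 5 FPKM, as the pseudocount shrinks folds. It became 59 without a filter, 273 with array weights, 228 with limma-voom and 331 with limma-voom and the block. With a minimum of 1.5-fold it became 482, and 977 with the block. Leaving out 1 library gave 2 to 117. With limma-voom 55.1% of 1015 calls were upward (559 upward, 456 downward), against 43.0% in the main test.

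The RBM8A log2 fold change kept its sign under all 23 alternatives and lost its call without siRBM8A replicate 3 (-2.05, adjusted p = 0.0544, range over the alternatives 9.16e-10 to 0.0544); over the libraries left out it ran from -2.05 to -1.83. Over the libraries left out, the number of called lists ran from 9 to 13. It was 0 with an estimated correlation and 0 with the block and an estimated correlation, both with fewer degrees of freedom, and 8 with fry. With the replicate block 11 lists were called: those of Wnt targets, p53 targets and NF-kB genes were lost and that of splicing factors was gained. CASC3 was gained, more list members passed the test, and the block changed no other call of a list or a named gene. With the block and the GC correction 14 lists were called: all 13 kept their call and that of TGF-beta and BMP targets was gained (0.0301, and 0.0291 with the GC correction alone), while that of splicing factors was not called (0.527). MAGOH was gained with the GC correction (0.0455), with the block as well (0.0366) and with array weights (0.0286), which also gained EIF4A3 (0.0119). The GC correction also gained CASC3 (0.00178, and 0.00395 with the block).

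Reversals touched only results that were not called. The MAGOHB log2 fold change was 0.153 with the GC correction, with or without the block, and ran from -0.22 to 0.0445 over the libraries left out, the highest without siRBM8A replicate 2. That of EIF4A3 ran from -0.0316, without siRBM8A replicate 2, to 0.18. List directions turned for the decay factors with fry (adjusted p = 0.601), for PI3K, AKT and mTOR components at a mean of at least 5 FPKM (0.693), for epithelial genes with limma-voom and the block (0.808), and for immediate early genes with the GC correction (0.785, and 0.910 with the block). With 1 library left out they turned for homologous recombination (0.829 and 0.851, range 0.119 to 0.851), epithelial genes (0.829 and 0.846, range 0.353 to 0.897) and immediate early genes (0.842 and 0.902, range 0.239 to 0.902). Of 69 named genes other than RBM8A, 63 lost their call without siRBM8A replicate 3, 60 without siNC replicate 3, 59 without siNC replicate 1 and 29 without a filter. Among the 69 were MAGOH, MAGOHB, EIF4A3 and CASC3, which had no call to lose. Genes at few fragments, such as ORM2 with 32 in siRBM8A, are limited by depth.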

Other observations

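Tests of snoRNA hosts, exon number and gene class, and of the shared deviation by replicate, were chosen after the result was seen. Most genes of every class were not called, and the balance of the calls differed between classes. Of 977 tested long non-coding RNA genes 56 rose and 13 fell, while of 10439 protein-coding genes 217 rose and 386 fell (Fisher's exact test on the called genes, p = 4.69e-13, adjusted p = 1.88e-12 over 4 classes). Of 187 transcribed pseudogenes 8 rose and 2 fell (Fisher's exact test, p = 0.00636, adjusted p = 0.00848). Of 597 other pseudogenes 19 rose and 2 fell (Fisher's exact test, p = 5.42e-07, adjusted p = 1.08e-06). Of 478 genes of the remaining biotypes 5 rose and 1 fell (Fisher's exact test, p = 0.0263, adjusted p = 0.0263). The called long non-coding RNA genes include antisense ones, whose values are uncertain because the strand setting is not given. Genes are not independent replicates. After scaling to equal FPKM sums, 77 long non-coding RNA genes rose and 12 fell, and 347 coding genes rose and 308 fell, so that the majority of coding calls turned upward with this scaling. With the replicate block and the GC correction these counts were 206 and 77 for long non-coding RNA genes and 2150 and 2482 for coding genes.

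Non-coding hosts of snoRNAs outside the lists included EPB41L4A-AS1, which rose from 3.58 ± 0.105 FPKM by a log2 fold change of 1.39 (SE 0.0875), and SNHG7, which rose from 8.61 ± 0.694 to 21.1 ± 3.59 FPKM (log2 fold change 1.19, SE 0.137). LRRC75A-AS1, SNHG6 and SNHG26 also rose, and these 5 were named after their values were seen. Without siRBM8A replicate 3 none of the 5 was called, and without siNC replicate 1 or 3 EPB41L4A-AS1 alone was. SNHG26 lost its call whichever library was left out. Of 18 such hosts 5 rose and 0 fell, with 13 above 0 and a median log2 fold change of 0.26. One hypothesis is that non-coding snoRNA hosts may rise as a class. Their median exceeded that of 180 coding hosts by 0.30 (permutation test with 100000 resamples, p = 0.00067, adjusted p = 0.00268 over 4 comparisons). It exceeded that of 951 other non-coding RNA genes by 0.16, which did not pass (permutation test, p = 0.152, adjusted p = 0.203). With hosts limited to those whose snoRNA lies outside every annotated exon, the differences were 0.26 (adjusted p = 0.0185) and 0.10 (adjusted p = 0.441). The hosts thus differed from coding hosts, and a difference from other non-coding RNA genes was not shown.

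Calls among genes with many exons were mostly downward. Of 1306 coding genes with over 20 exons in the longest transcript 10 rose and 87 fell, with a median log2 fold change of -0.14, or -0.12 after the GC correction. Of 3095 genes with 2 to 5 exons 84 rose and 98 fell. The hypothesis that exon number may go with the fold change beyond GC content, transcript length, intron length and mean level was tested by a slope in each replicate pair. The slope per doubling of exon number was -0.03, -0.02 and -0.02, with a mean of -0.025 (SE 0.00432 over 3 pairs). The slope is small, and other properties of long genes were not in the model.

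The first pattern weighed is the shared deviation of libraries with the same replicate number, with a mean correlation of 0.424. Removing the GC trend of each library lowered it to 0.193 (jackknife SE over 23 chromosomes 0.0203), above the bound of 0.1. The correlation was 0.215 (SE 0.0278) for replicate 1 and 0.335 (SE 0.0180) for replicate 2 after the correction, both above the bound. The SE covers spread over chromosomes, not over libraries. The correction used the GC content of the longest transcript and may leave part of a GC trend. Every correlation between the groups kept its sign and shrank, so library-wise GC bias as the whole cause stays open. For replicate 3 the correlation was 0.0275 (SE 0.0295) after and 0.102 (SE 0.0252) before. A shared deviation was thus not clearly above the bound to begin with and GC bias stays open there too, while siNC replicate 3 with siRBM8A replicate 1 gave 0.108. The labels name no shared day or batch for a number, and no biological explanation was tested.

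The second pattern is that the replication list was higher and the mitotic list lower than other genes by camera. Neither was called with an estimated correlation (adjusted p = 0.126 and 0.490, camera), which was 0.0127 and 0.352. For the replication list this estimate was close to the preset 0.01, and that setting also has fewer degrees of freedom. The difference between the 2 list medians was 0.639, 0.669 and 0.628 on the log2 scale in the pairs of replicates 1, 2 and 3. With the GC trend removed it was 0.577 (SE 0.00570 over 3 pairs), above the bound of 0.323 set from its uncorrected mean of 0.645, which argues against library-wise GC bias as the whole cause. The smaller of the differences in the pairs of replicates 1 and 3 was 0.938 times that in the pair of replicate 2, which argues against an origin in the replicate 2 libraries alone. A change in the share of cells in each phase, or in transcript levels within phases, stays open as a hypothesis, and neither was measured here.

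The third pattern is the lower interferon list, which was not called with an estimated correlation (adjusted p = 0.121, camera). That estimate, 0.00518, was below the preset 0.01, so correlation between members does not account for the loss of the call. The setting also takes its degrees of freedom from the few libraries, which raises p for any list. With the GC trend removed the list median was -0.42 (SE 0.0213 over 3 pairs), against -0.48 without, which argues against library-wise GC bias as the whole cause. Fewer leukocytes in the siRBM8A cultures are unlikely by design, as AGS is an established cell line, so the check of leukocyte genes had little to decide. In it, 7 leukocyte genes summed to 3.09 ± 0.546 FPKM in siNC and 3.11 ± 1.02 FPKM in siRBM8A. The siNC sum was below the bound of 46.7 FPKM, set as 10% of the fall of 467 in summed interferon FPKM. CSF1R, the highest of the 7, was at 2.55 FPKM in siNC. With 1 siRNA against RBM8A in the design, loss of RBM8A cannot be told apart from a different immune stimulation by the 2 siRNAs.

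For the number of genes changed, 1 of the 10 splits of the 6 libraries gave as many as the 709 genes of the real split, the real one itself, and the highest other split gave 0 by limma. At an unadjusted p under 0.05 the real split gave 3329 genes, and the highest other, the 2 replicate 2 libraries with siRBM8A replicate 3 against the rest, gave 3183. For at least 2-fold changes, 1 of 10 splits reached the real count of 90, with 0 as the highest other. For gene lists, 1 of 10 splits called as many as the 13 of the real split, and the highest other called 11, the split of siNC replicates 1 and 3 with siRBM8A replicate 2 against the rest. The lowest other called 4, so every split gave called lists. In all, 4 splits parted all 3 pairs. The other 3 of these called 0 genes with and without the replicate block and 5 to 11 lists, while the real split called 5096 genes with the block. The other 6 splits parted 1 pair. With 10 splits the share cannot fall under 0.05.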
